A study of Arabidopsis thaliana with 15 samples.

How the data were processed

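Gene expression was measured on Affymetrix ATH1 arrays in 5 populations of cells sorted by fluorescence from protoplasts of Arabidopsis thaliana seedlings, with 3 arrays per population. Per the labels' protocols, plants in the Col background grew for 14 days at 25 °C on 1% sucrose under a cycle of 16 hours of light and 8 hours of darkness. Aerial tissue was digested for 2 hours, and each replicate held between 2000 and 20000 sorted cells. RNA was purified on RNeasy Micro columns, checked on a Bioanalyzer, amplified with the NuGEN Ovation Pico WTA system and labelled with the Encore biotin module, again per the labels' protocols. Each population carried its own reporter. The epidermis was sorted with a membrane YFP under the ML1 promoter, early precursors with a SPCH-YFP fusion under the SPCH promoter, and middle precursors with a nuclear GFP under the MUTE promoter. Late precursors were sorted with a GFP-FAMA fusion under the FAMA promoter, and mature guard cells with the E1728 enhancer trap. The SPCH-YFP and GFP-FAMA transgenes carry coding sequence of the gene they report, so their transcripts can add to the signal of the SPCH and FAMA probe sets in those sorts. Each population is also its own reporter line, so effects of the line on any gene cannot be told apart from those of the stage.

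The deposited values are 1 log2 expression value per probe set and array, which the authors made with RMA in the affy package, per the submitters' processing notes. The notes give no version of either. The log base is inferred from the use of RMA and from the range of the values, 1.11 to 13.4. The table holds 20956 probe sets, and the medians of the 15 arrays lie between 2.52 and 2.68. It holds 0 Affymetrix control probe sets and 0 probe sets whose names mark shared or cross-hybridising probes. RNA integrity therefore could not be measured from the control transcripts. For arrays, the number of replicates limits the precision.

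The probe annotation assigns 12783 probe sets to 1 gene and 37 to several, and lists no gene for 8136. Of the 12783, 12720 were found in the reference list of genes and 1538 have a symbol beyond the locus code. All probe sets entered the tests, and only those listed to 1 gene could be named. No genome build is stated, so no coordinates are given.

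All 15 arrays entered 1 linear model in limma 3.58.1 (R 4.3.3, with values read by version 1.17.8 of data.table) with 1 mean per group, which left 10 residual degrees of freedom. Lineage stages were compared with the epidermis, and each stage with the stage before it, giving 7 comparisons, each tested with limma's moderated test after empirical Bayes. A moderated F test took the 4 lineage stages together. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05 on the adjusted p. Errors of fold changes are standard errors (SE) from this model, and errors of group levels are standard deviations (SD).

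Genes to be named were chosen by a rule. For each comparison it took up to 5 rises and 5 falls with the greatest log2 fold change among probe sets that passed the test, map to 1 gene with a symbol, and had all 3 arrays of a group above all 3 of the other. It also took up to 2 rises and 2 falls from each gene list, and the lineage genes and guard cell channels where measured. SPCH, MUTE and FAMA (listed under the symbol FMA) were measured. No probe set was listed to ATML1, TMM, BASL, EPF1, EPF2, MYB60, KAT1, KAT2, SLAC1 or GORK. For the 4 stages together the rule took the 3 symbols with the widest range of stage means among those highest in each stage.

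The rule, the comparisons, the tests, the threshold and 15 gene lists were fixed before the data were examined. Those lists name 370 genes, of which 38 have a probe set of 1 gene. List members were dropped where the reference table gives the locus a symbol that is neither the listed symbol nor a synonym of it, which removed 5 members, 1 of them measured. Another 12 lists, taken from gene names in the reference table, were made after the annotation had been read but before any expression value was examined. Lists with at least 3 measured members were tested with camera at its preset correlation of 0.01 on a table of 12668 genes, using the brightest probe set of each gene. That covers 4 of the 15 lists (G2/M cell cycle, DNA replication, photosynthesis, ribosome and nucleolus) and all 12 others. The 12 are plastid-encoded photosynthesis, nuclear chloroplast function, mitosis and cytokinesis, replication and histones, cytosolic ribosomal proteins, autophagy, protein folding, dehydration and cold response, pathogen and wound response, expansins and XTH, sugar transport, and UDP-glycosyltransferases. Adjustment was within a comparison and within each of these list families, over 112 pairs of list and comparison. Camera was rerun with an estimated correlation, and fry was run beside it. Another 10 of the 15 lists had 1 or 2 measured members, 17 genes in all, reported gene by gene: early stomatal lineage, guard mother cell, mature guard cell, cell cycle inhibitors and endocycle, epidermis and cuticle, trichome, vascular, wounding and stress, auxin transport and response, and starch and malate metabolism. The ABA signalling list had 0 measured members. Some lists share genes: the nuclear chloroplast list holds all 9 photosynthesis genes, the mitosis list all 5 G2/M genes, the ribosomal protein list all 3 genes of the ribosome and nucleolus list, and the histone list 3 of the 4 DNA replication genes.

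Alternatives changed 1 choice at a time: only the compared groups in the fit, replicate number as a block, probe sets below the 40th percentile of mean signal left out, cyclic loess on top of the deposited values, empirical Bayes with trend and robust settings, array weights, a minimum of a 2-fold difference, and each array left out in turn. For lists, the mean of a gene's probe sets replaced the brightest. The following were chosen after seeing the data: a fit without the early precursor arrays, 1 weight per group, and averaging of late precursor replicates 2 and 3. The tests were also checked on simulated data with the group spreads of these arrays, in which 200 of 20956 probe sets were changed, 100 by 2-fold and 100 by 4-fold.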

Results

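Expression was profiled in 15 ATH1 arrays of sorted seedling protoplasts, 3 arrays in each of 5 populations. They are the epidermis as a whole and 4 successive stages of the stomatal lineage: early precursors (meristemoid mother cells and young meristemoids), middle precursors (older meristemoids and newly formed guard mother cells), late precursors (guard mother cells ready to divide and guard cells that have just formed) and mature guard cells. Values are log2 expression from RMA for 20956 probe sets, with array medians between 2.52 and 2.68. A group mean at or below 2.68, the highest array median, is read as near the background, a bound chosen after seeing the data; no control probe sets were at hand to measure the background. A fold, log2 change or range of a single gene that rests on such a mean is given as at least the printed value. The labels do not say whether the replicates came from separate cultures, so each p-value measures a difference against the spread between these samples.

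The genes whose promoters drove the reporters were followed first, to see where each sort lies in the lineage. SPCH, the basic helix-loop-helix regulator of entry into the lineage, stood at 9.11 ± 0.10 in early precursors (SD, n = 3), 4.1 ± 0.63 in middle precursors, 2.31 ± 0.09 in late precursors, 2.52 ± 0.31 in mature guard cells and 2.27 ± 0.20 in the epidermis. MUTE, the related regulator of the meristemoid to guard mother cell step, was near the background in all 5 groups, with means from 1.54 ± 0.07 in late precursors to 2.37 ± 0.43 in middle precursors. FAMA, which acts at the last division and in guard cell identity, went from 2.29 ± 0.38 in early precursors through 6.64 ± 0.26 in middle precursors to 10.11 ± 0.26 in late precursors. It stood at 7.23 ± 0.31 in mature guard cells and 3.19 ± 0.18 in the epidermis. CHX20, a cation/proton exchanger of guard cells, was at 10.03 ± 0.14 in late precursors and 9.66 ± 0.26 in mature guard cells, against 6.54 ± 0.14 in the epidermis. CHX20 was named by the rule from these same values and is in no fixed gene list. GC1 (AT1G22690) and BLUS1 (AT4G14480), the measured genes of the mature guard cell list, had 0 calls against the epidermis in either stage. Adjusted over the list alone, 2 were higher in late precursors and 1 in mature guard cells. GC1 averaged 9.07 ± 1.08 and 8.82 ± 0.57 in these stages, against 5.78 ± 0.46 in the epidermis. The early and late sorts carry SPCH and FAMA transgenes whose transcripts can add to the SPCH and FAMA values. Each population came from its own reporter line, so line and stage cannot be told apart for any gene.

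**Figure D1:**
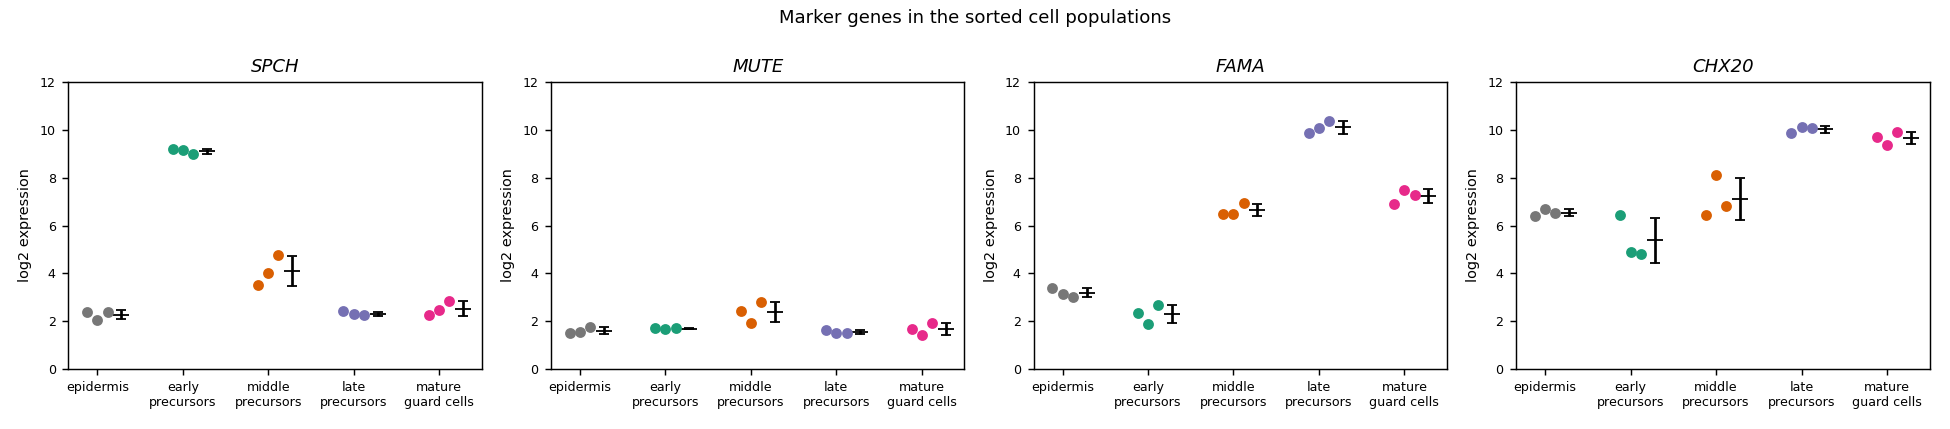
Log2 expression of SPCH, MUTE, FAMA and CHX20 on each of the 15 arrays (points), with group mean and SD (black bars, n = 3). The SPCH mean is highest in early precursors at 9.11, those of FAMA and CHX20 in late precursors at 10.11 and 10.03, and the MUTE means, at most 2.37, are near the background.

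Early precursors were the most variable population. Their residual SD was 0.658, against 0.282 in middle precursors, 0.295 in late precursors, 0.344 in mature guard cells and 0.383 in the epidermis. Pearson's r between early precursor replicates, taken across probe sets, which are not independent replicates, lay between 0.820 and 0.867, and in every other group it was at least 0.948. Late precursor replicates 2 and 3 were closer to each other than any other pair, with r = 0.994 and an SD of their difference of 0.209, against 0.357 for the next closest pair. On the first principal component, with 34.6% of the variance, early precursors lay lowest, and late precursors and mature guard cells highest. Middle precursors (0.42 to 3.27) lay between them and overlapped with the epidermis (-17.9 to 10.8). The second component, with 16.4%, set the epidermis apart.

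**Figure D2:**
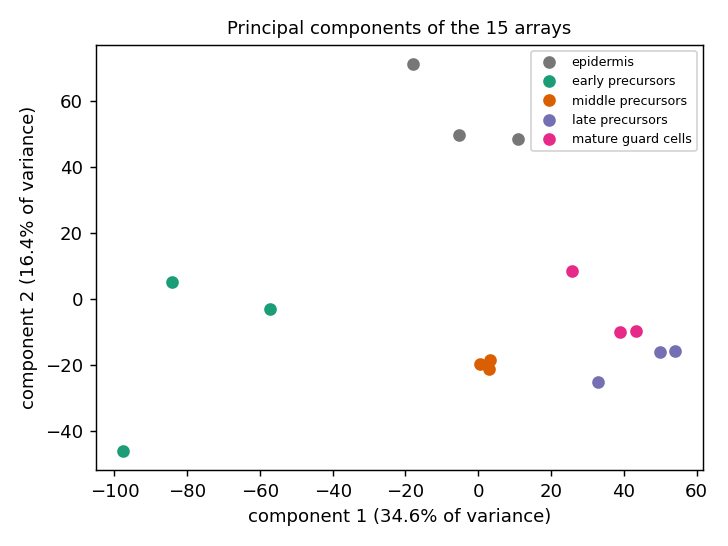
First and second principal components of the 15 arrays, 1 point per array, coloured by population, axes in component scores. Early precursor arrays lie between -97.5 and -57.3 on the first component, and epidermis arrays between 48.5 and 71.4 on the second.

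**Figure D3:**
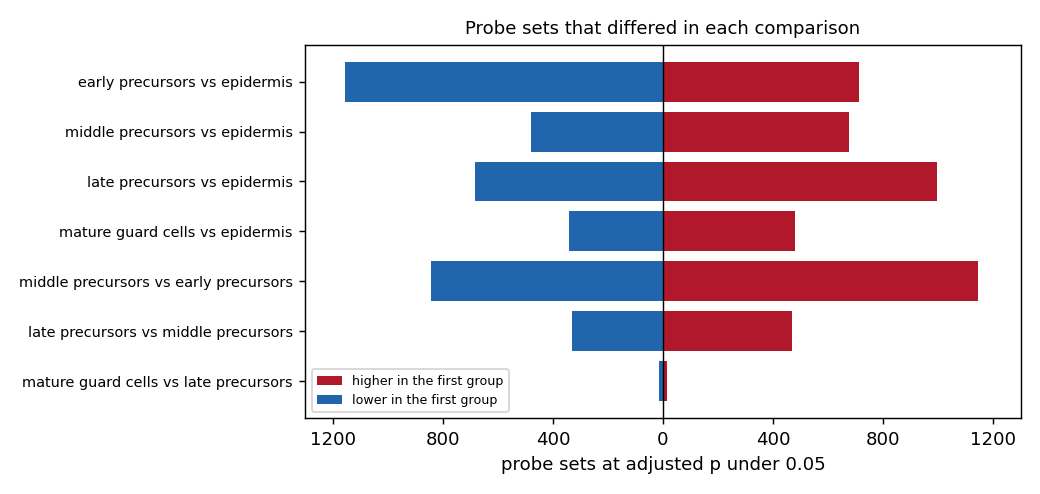
Number of probe sets with a limma adjusted p under 0.05 in each of the 7 comparisons, higher in the first group to the right and lower to the left. Counts run from 29 between mature guard cells and late precursors to 1991 between middle and early precursors.

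Early precursors were compared with the epidermis to ask what marks cells at the start of the lineage. SPCH was at least 115-fold higher (adjusted p = 4.05e-08), and ATLP-1, which encodes a thaumatin-like protein, was at least 28-fold higher at 7.16 ± 0.47 against 2.36 ± 0.11 (SD, n = 3; adjusted p = 9.62e-07). The SPCH-YFP transgene of the early sort can add to the SPCH difference. UBC20, a ubiquitin-conjugating enzyme gene, stood at 7.56 ± 0.18 against 3.65 ± 0.49, and the chromosomal protein gene 3xHMG-box2 at 9.32 ± 0.04 against 5.94 ± 0.17. Among the greatest falls, SBPASE, a Calvin cycle enzyme, was 14.2-fold lower and CCT2, which makes CDP-choline for phosphatidylcholine, 12.3-fold lower. GT72B1, a UDP-glycosyltransferase, HL, and the sulfiredoxin gene SRX were 10.8-fold, 9.38-fold and 8.75-fold lower. EXPB3, a β-expansin, and VPS2.2, an ESCRT-III component, rose by 3.92 (SE 0.65) and at least 3.81 (SE 0.55) on the log2 scale.

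The G2/M and mitosis lists were higher in early precursors, and the lists of replication genes did not pass with camera. Of the 5 measured G2/M genes 4 rose, the same number adjusted over the list alone, with a mean log2 fold change of 2.12 (camera adjusted p = 4.27e-06; adjusted p = 0.00274 with an estimated correlation). The mitosis and cytokinesis list, which contains those 5, had 9 of 25 members higher and 1 lower, with a mean of 0.91 (adjusted p = 0.000291; adjusted p = 0.0318 with an estimated correlation). Examples are 3xHMG-box2 and KINESIN-12B, a motor of the phragmoplast, which was 4.3-fold higher (adjusted p = 3.38e-05). The member that fell was KEU, a regulator of cytokinetic vesicle fusion (-1.22, adjusted p = 0.0485). The KEU call was lost in 12 alternative fits, among them those without epidermis replicate 1 (0.159), 2 (0.103) or 3 (0.0626) or early precursor replicate 1 (0.119) or 2 (0.141). Neither the 4 DNA replication genes (0 called, 0 over the list alone; camera adjusted p = 0.56) nor the replication and histone list (adjusted p = 0.332; 0.01 with fry) passed with camera. The DNA replication list averaged 2.14 to 2.46 in all 5 groups, below the bound of 2.68, so its results here and in the comparisons below do not show that these genes stayed level. Cytosolic ribosomal protein genes rose in 30 of 104 cases, with a mean of 0.65 (adjusted p = 5.42e-09; adjusted p = 0.136 with an estimated correlation). AT3G16780 and AT1G77940 among them rose by 2.59 (SE 0.45) and 2.21 (SE 0.46). The ribosome and nucleolus list, 3 of those genes, had 1 called and 2 over the list alone (camera adjusted p = 0.0255; adjusted p = 0.187 with an estimated correlation). That call was lost without epidermis replicate 1 (adjusted p = 0.0673), epidermis replicate 3 (0.0566), early precursor replicate 2 (0.0554) or early precursor replicate 3 (0.18).

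Photosynthesis genes, which are also abundant in mesophyll, fell in early precursors. All 9 measured members of the photosynthesis list fell adjusted over the list alone and 6 over all probe sets, with a mean of -2.06 (camera adjusted p = 2.25e-09; adjusted p = 0.0509 with an estimated correlation). PSAE-1, a photosystem I subunit, was 6.10-fold lower (adjusted p = 0.00342). In the wider nuclear chloroplast list 18 of 39 fell (adjusted p = 1.98e-17; adjusted p = 0.0795 with an estimated correlation), and 13 of 45 plastid-encoded genes fell (adjusted p = 2.77e-17; adjusted p = 0.136 with an estimated correlation). Autophagy genes fell by a mean of 0.76 with 2 of 11 called (adjusted p = 0.0012; adjusted p = 0.136 with an estimated correlation). An example is ATG8F, an autophagosome protein gene (-1.94, SE 0.36).

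In all, 1868 of 20956 probe sets differed between early precursors and the epidermis, 713 higher and 1155 lower. The count was 273 with only these groups in the fit, 863 with array weights, 770 with 1 weight per group and 1168 without epidermis replicate 2. EXPB3, VPS2.2, SBPASE, GT72B1, SRX, PSAE-1, ATG8F and AT1G77940 did not pass with only these groups in the fit (adjusted p from 0.0533 for SRX to 0.152 for AT1G77940), nor AT3G16780 with 1 weight per group (0.0532). On simulated data with these spreads, 92% of 4-fold and 50% of 2-fold changes were found. However, 158 calls, 52.7% of all calls in the simulation, were false. With only these groups in the fit 0 calls in the simulation were false, but 35 of the 100 4-fold changes were found. The false share depends on how many probe sets truly change, which is not known for the data. It therefore does not give the share of false calls among the reported ones.

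Middle precursors were compared with the epidermis to ask what marks cells at the meristemoid to guard mother cell step. FAMA was 10.9-fold higher (adjusted p = 9.19e-06) and SPCH at least 3.56-fold higher (adjusted p = 0.00166). The subtilisin-like protease gene SBT1.3 was at least 12.8-fold higher at 6.06 ± 0.52 against 2.38 ± 0.29 (SD, n = 3), and XTH16, a xyloglucan endotransglucosylase gene of the cell wall, at least 6.81-fold higher at 5.43 ± 0.27 against 2.66 ± 0.22. UBC20 and APK1A rose by 2.57 (SE 0.31) and 2.53 (SE 0.31). ECS1 and TAPX, a thylakoid ascorbate peroxidase gene, were 7.16-fold and 5.03-fold lower.

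The G2/M, mitosis, replication and histone, and ribosomal protein lists were raised in middle precursors. Of the 5 G2/M genes 2 rose, and 4 adjusted over the list alone, with a mean of 1.46 (camera adjusted p = 7.86e-06; adjusted p = 0.00332 with an estimated correlation), as did 4 of 25 mitosis genes (mean 0.61, adjusted p = 4.13e-05; adjusted p = 0.0123 with an estimated correlation). KINESIN-12B was 4.06-fold and 3xHMG-box2 4.49-fold higher. The replication and histone list rose with 5 of 14 called (mean 0.64, adjusted p = 0.000172; adjusted p = 0.0123 with an estimated correlation), and HTB2, a histone H2B gene, was 5.26-fold higher. PRL, which encodes the replicative helicase subunit MCM7, rose by at least 1.21 (SE 0.23), the single call among 4 DNA replication genes on either adjustment (camera adjusted p = 0.201). Their mean was 0.27 and their median -0.00318. Ribosomal protein genes rose by a mean of 0.69 with 12 of 104 called (adjusted p = 1.13e-19; adjusted p = 0.0434 with an estimated correlation). Within them, the ribosome and nucleolus list had 1 of 3 called on either adjustment (camera adjusted p = 0.00592; adjusted p = 0.107 with an estimated correlation).

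Chloroplast genes were lower in middle precursors. All 9 photosynthesis genes fell adjusted over the list alone and 6 over all probe sets, with a mean of -1.97 (camera adjusted p = 1.03e-07; adjusted p = 0.0805 with an estimated correlation). Plastid-encoded genes fell in 27 of 45 cases (adjusted p = 1.14e-24; adjusted p = 0.0706 with an estimated correlation), among them ndhJ and ndhK, subunits of the plastid NDH complex (-2.21 and -1.99). Nuclear chloroplast genes fell in 12 of 39 cases (adjusted p = 5.29e-11; adjusted p = 0.104 with an estimated correlation). RCA, which encodes Rubisco activase, fell by 2.29 on the log2 scale (adjusted p = 0.046), a call lost without epidermis replicate 1 (0.107), epidermis replicate 3 (0.158), or middle precursor replicate 1 (0.142), 2 (0.1) or 3 (0.122), and with late precursor replicates 2 and 3 averaged (0.0648).

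MUTE passed between middle precursors and the epidermis (2.37 ± 0.43 against 1.60 ± 0.14, SD, n = 3; adjusted p = 0.0386), but both means are near the background and no fold is given. The MUTE call was lost without epidermis replicate 1 (0.11), 2 (0.0865) or 3 (0.0654) and without middle precursor replicate 1 (0.118) or 3 (0.153), with only these groups in the fit (0.0958), and with late precursor replicates 2 and 3 averaged (0.0582). In all, 1157 probe sets differed, 678 higher and 479 lower; cyclic loess gave 519 higher and 652 lower, which turns the higher share from 58.6% to 44.3%. Other settings gave 2286 with array weights, 2496 without the early precursor arrays, 1986 with 1 weight per group, and 627, 547, 658 and 502 without epidermis replicate 3 and middle precursor replicates 1, 2 and 3. On simulated data 84% of 4-fold and 44% of 2-fold changes were found.

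Late precursors were compared with the epidermis to ask what marks guard mother cells and young guard cells. FAMA was 122-fold higher (adjusted p = 7.27e-09) and CHX20 11.2-fold higher (adjusted p = 0.000625). The GFP-FAMA transgene of the late sort can add to the FAMA difference. UGT73D1, a UDP-glycosyltransferase gene, stood at 7.29 ± 0.41 against 3.72 ± 0.27, and ALDH3F1, an aldehyde dehydrogenase gene, at 6.39 ± 0.21 against 3.22 ± 0.26 (SD, n = 3), 11.8-fold and 8.98-fold higher. The expansin gene EXPA16 rose by 2.08 (SE 0.31) and MYC3, a transcription factor of jasmonate signalling, by 2.19 (SE 0.32). ECS1 was at least 20.6-fold lower at 2.63 ± 0.57 against 6.99 ± 0.08 (adjusted p = 0.000119).

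In late precursors chloroplast lists were lower and the autophagy list higher at the preset correlation, and none of them passed with an estimated correlation. Of 9 photosynthesis genes 8 fell, and all 9 adjusted over the list alone, with a mean of -2.24 (camera adjusted p = 2.31e-08; adjusted p = 0.134 with an estimated correlation). Plastid-encoded genes fell in 40 of 45 cases (mean -1.21, adjusted p = 3.42e-34; adjusted p = 0.0798 with an estimated correlation), ndhJ by 2.33 on the log2 scale. Nuclear chloroplast genes fell in 22 of 39 (mean -1.51, adjusted p = 1.26e-13; adjusted p = 0.11 with an estimated correlation). Autophagy genes rose with 3 of 11 called (mean 0.97, adjusted p = 2.06e-05; adjusted p = 0.107 with an estimated correlation), among them ATG8B, at least 4.67-fold higher. The G2/M, mitosis, replication and histone, DNA replication, ribosome and nucleolus, and ribosomal protein lists did not pass in late precursors (camera adjusted p from 0.224 to 0.838). Adjusted over the list alone, 0 of the G2/M, DNA replication, and ribosome and nucleolus genes passed, as over all probe sets. The ribosomal protein list did pass without epidermis replicate 2 (mean 0.21, adjusted p = 0.00333).

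Between late precursors and the epidermis 1679 probe sets differed, 995 higher and 684 lower, and cyclic loess gave 777 higher and 810 lower, moving the higher share from 59.3% to 49.0%. The count was 4710 with array weights, 2924 without the early precursor arrays, 2626 with 1 weight per group and 858 with late precursor replicates 2 and 3 averaged, and it was 878, 882 and 893 without epidermis replicate 3, late precursor replicate 2 and late precursor replicate 3. On simulated data 88% of 4-fold and 46% of 2-fold changes were found.

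Mature guard cells were compared with the epidermis to ask what marks the end of the lineage. FAMA was 16.6-fold higher (adjusted p = 5.49e-06), CHX20 8.72-fold (adjusted p = 0.0025) and UGT73D1 7.01-fold (adjusted p = 0.000419). EXPA16 stood at 5.64 ± 0.61 against 3.18 ± 0.31 and APK1A at 7.99 ± 0.33 against 5.66 ± 0.61 (SD, n = 3). ALDH7B4, an aldehyde dehydrogenase gene, rose by 1.77 (SE 0.28). ECS1 was 6.92-fold lower, and the plastid NDH genes ndhJ and ndhK 4.80-fold and 4.05-fold lower.

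Plastid-encoded genes fell in 32 of 45 cases in mature guard cells (mean -1.13, camera adjusted p = 8.75e-33; adjusted p = 0.157 with an estimated correlation). Of 9 photosynthesis genes 1 fell over all probe sets and all 9 adjusted over the list alone (mean -1.60, adjusted p = 1.7e-05; adjusted p = 0.282 with an estimated correlation), and 4 of 39 nuclear chloroplast genes fell (adjusted p = 1.53e-07; adjusted p = 0.22 with an estimated correlation). Autophagy genes rose by a mean of 0.59 with 1 of 11 called (adjusted p = 0.00346; adjusted p = 0.22 with an estimated correlation), and ribosomal protein genes by 0.30 with 0 of 104 called (adjusted p = 2.89e-06; adjusted p = 0.239 with an estimated correlation). Neither passed with cyclic loess (0.0524 and 0.203) or with fry (0.093 and 0.154). The replication and histone list passed narrowly (mean 0.34, adjusted p = 0.0423; adjusted p = 0.157 with an estimated correlation). That call was lost with cyclic loess (0.0843), with dim genes left out (0.103) and without epidermis replicate 2 (0.0976) or 3 (0.0775) or mature guard cell replicate 1 (0.1) or 3 (0.0699). The 5 G2/M genes had 0 called and 1 adjusted over the list alone, and the DNA replication and the ribosome and nucleolus lists 0 on either adjustment. These lists and the mitosis list did not pass (camera adjusted p from 0.0788 to 0.614). The ribosome and nucleolus list did pass without epidermis replicate 2 (0.0148) or mature guard cell replicate 1 (0.0282), and the mitosis list without mature guard cell replicate 2 (0.0419).

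In all, 820 probe sets differed between mature guard cells and the epidermis, 480 higher and 340 lower, against 323 higher and 425 lower with cyclic loess, a higher share of 58.5% against 43.2%. Alternatives gave 533 with only these groups, 1468 with array weights and 1944 without the early precursor arrays, and 313, 309 and 346 without epidermis replicate 3, mature guard cell replicate 1 and mature guard cell replicate 2. On simulated data 84% of 4-fold and 47% of 2-fold changes were found.

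Middle were compared with early precursors to ask what changes as meristemoids move towards the guard mother cell. SPCH fell 32.3-fold, from 9.11 ± 0.10 to 4.1 ± 0.63, while FAMA rose at least 20.3-fold, from 2.29 ± 0.38 to 6.64 ± 0.26 (SD, n = 3; adjusted p = 7.77e-07 for each). The SPCH-YFP transgene of the early sort can add to the SPCH fall. ATLP-1 fell 15.5-fold (adjusted p = 6.79e-06). GSTU25, a glutathione transferase gene, rose 13.5-fold, LTI30, a dehydrin gene, 12.6-fold from 6.84 ± 0.85 to 10.49 ± 0.11, and GT72B1 10.3-fold. The β-glucosidase gene BGLU25 rose by 3.44 (SE 0.47), and DPE1, an enzyme gene of starch breakdown, by 1.89 (SE 0.36).

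The dehydration and cold list and the autophagy list were higher in middle than in early precursors at the preset correlation. Neither passed with an estimated correlation. The dehydration and cold list rose with 2 of 18 called (mean 0.81, camera adjusted p = 8.48e-05; adjusted p = 0.146 with an estimated correlation) and the autophagy list with 3 of 11 (mean 0.87, adjusted p = 0.000652; adjusted p = 0.157 with an estimated correlation). Pathogen and wound genes did not pass, with 3 of 24 higher and 1 lower (camera adjusted p = 0.137), and STZ and WRKY53 of the wounding and stress list had 0 calls on either adjustment. The replication and histone list rose with 4 of 14 called (mean 0.33, adjusted p = 0.0295; adjusted p = 0.146 with an estimated correlation), a call lost without early precursor replicate 1 (0.0557) and with dim genes left out (0.169). PRL rose by at least 1.24 (SE 0.23) but did not pass with only these groups in the fit (0.0807), with array weights (0.0759) or with 1 weight per group (0.0541). It was the 1 call on either adjustment among 4 DNA replication genes, which had a mean of 0.14 and a median of -0.16 (camera adjusted p = 0.779). The G2/M genes had a mean of -0.66 with 1 of 5 called on either adjustment (camera adjusted p = 0.669), but passed with cyclic loess (mean -0.84, adjusted p = 0.0456) and with fry (0.0446). Ribosomal protein genes went both ways, 5 higher and 6 lower (mean 0.04, adjusted p = 0.16), and the mean was -0.35 with cyclic loess (adjusted p = 0.000629). The list passed as higher without early precursor replicate 3 (0.023) or middle precursor replicate 2 (0.00516). The 3 genes of the ribosome and nucleolus list had 0 called on either adjustment (mean -0.11, adjusted p = 0.988; with cyclic loess -0.59 and 0.0456), and the 9 photosynthesis genes likewise (mean 0.09, adjusted p = 0.669). Plastid-encoded genes had a mean of -0.26 (adjusted p = 0.0583), and -0.65 with cyclic loess (adjusted p = 1.64e-14); they passed also with the replicate block (0.0383), with dim genes left out (0.00289), and without early precursor replicate 2 (0.000156) or middle precursor replicate 2 (0.026) or 3 (0.04). Nuclear chloroplast genes passed with a mean of 0.18 (adjusted p = 0.0295; adjusted p = 0.751 with an estimated correlation, 0.649 with fry). Their mean turned to -0.20 with cyclic loess (0.648) and to -0.10 without early precursor replicate 2 (0.522), and the call was lost without early precursor replicate 1 (0.0536) or middle precursor replicate 3 (0.0921) and with dim genes left out (0.567).

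In all, 1991 probe sets differed between middle and early precursors, 1146 higher and 845 lower, 1154 of them by at least 2-fold. Alternatives gave 362 with only these groups, 1140 with cyclic loess, 770 with array weights, 651 with 1 weight per group, and 3765, 782, 1121 and 703 without early precursor replicate 3 and middle precursor replicates 1, 2 and 3. BGLU25 did not pass with only these groups (adjusted p = 0.0537). On simulated data 82% of 4-fold and 51% of 2-fold changes were found. There, 83 calls, 38.4% of all calls in the simulation, were false. That share depends on how many probe sets truly change, so it does not carry over to the reported calls.

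Late were compared with middle precursors to ask what changes around the last division of the guard mother cell. FAMA rose 11.1-fold (adjusted p = 1.72e-05), UGT73D1 17.7-fold from 3.14 ± 0.24 to 7.29 ± 0.41 (SD, n = 3), and CHX20 7.54-fold from 7.12 ± 0.89 to 10.03 ± 0.14. The GFP-FAMA transgene of the late sort can add to the FAMA rise. MGL, which encodes methionine gamma-lyase, rose at least 6.68-fold (adjusted p = 0.000225), and the glutathione transferase gene GSTU27 by 2.91 (SE 0.47). SPCH was at least 3.45-fold lower, and 3xHMG-box2, HTB2 and KINESIN-12B were 5.18-fold, 4.89-fold and 3.23-fold lower. The wall and protease genes XTH16, EXPA15 and SBT1.3 were 4.37-fold, 4.24-fold and 4.99-fold lower. AT1G22690, the guard cell gene GC1, went from 4.77 ± 1.17 to 9.07 ± 1.08 (adjusted p = 0.0351), a call lost without middle precursor replicate 1 (0.141) or 3 (0.141) or late precursor replicate 2 (0.143) or 3 (0.146), with the replicate block (0.0541) and with late precursor replicates 2 and 3 averaged (0.144).

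The G2/M and mitosis lists were lower as lists after this step, though most of their members were not called. The G2/M list fell with 2 of 5 called on either adjustment (mean -1.43, camera adjusted p = 2.12e-06; adjusted p = 0.00181 with an estimated correlation), and the mitosis list with 5 of 25 (mean -0.58, adjusted p = 0.000186; adjusted p = 0.0415 with an estimated correlation). The replication and histone list fell with 3 of 14 called (mean -0.32, adjusted p = 0.0117; adjusted p = 0.058 with an estimated correlation). Ribosomal protein genes fell from a mean level of 6.47 ± 0.30 to 5.85 ± 0.02 (SD, n = 3) with 7 of 104 called (adjusted p = 1.14e-18; adjusted p = 0.058 with an estimated correlation). The 3 genes of the ribosome and nucleolus list had 0 called and 1 adjusted over the list alone (camera adjusted p = 0.0167; adjusted p = 0.138 with an estimated correlation), a call lost without middle precursor replicate 1 (0.0516) or 3 (0.0521). Autophagy genes rose by a mean of 0.87 with 1 of 11 called (adjusted p = 4e-06; adjusted p = 0.058 with an estimated correlation). Plastid-encoded genes fell by a mean of 0.28 with 1 of 45 called (adjusted p = 1.23e-06; adjusted p = 0.408 with an estimated correlation, 0.203 with fry). DNA replication genes had 1 of 4 called on either adjustment and did not pass as a list (camera adjusted p = 0.104; 0.0319 with fry). Nuclear chloroplast genes did not pass (0.0609), but did without middle precursor replicate 2 (0.0298) or late precursor replicate 2 (0.0112) or 3 (0.00496), with the replicate block (0.0201) and with late precursor replicates 2 and 3 averaged (0.00685). The 9 photosynthesis genes had 0 called on either adjustment (camera adjusted p = 0.24).

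In all, 799 probe sets differed between late and middle precursors, 468 higher and 331 lower. Alternatives gave 1793 with only these groups, 4256 with array weights, 1412 without the early precursor arrays, 1938 with 1 weight per group and 327 with late precursor replicates 2 and 3 averaged, and 366, 366, 332 and 364 without middle precursor replicates 1 and 3 and late precursor replicates 2 and 3. On simulated data 88% of 4-fold and 45% of 2-fold changes were found.

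Mature guard cells were compared with late precursors to ask what changes as young guard cells mature. FAMA fell 7.36-fold, from 10.11 ± 0.26 to 7.23 ± 0.31 (SD, n = 3; adjusted p = 0.000283), and BCAT4, an enzyme gene of methionine chain elongation in glucosinolate synthesis, rose at least 3.3-fold, from 2.51 ± 0.22 to 4.23 ± 0.09 (adjusted p = 0.000283). Late precursors carry the GFP-FAMA transgene and mature guard cells do not, so the FAMA fall can reflect the transgene. CLE41, which encodes a signalling peptide precursor, rose by at least 1.39 (SE 0.19) and GTR1, a glucosinolate transporter gene, by 1.26 (SE 0.22). CHX20 averaged 10.03 and 9.66 in the 2 stages and the guard cell gene GC1 (AT1G22690) 9.07 ± 1.08 and 8.82 ± 0.57, differences that did not pass. The lists that passed with camera in this comparison did not pass with an estimated correlation or with fry. The mean was 0.47 for nuclear chloroplast genes (camera adjusted p = 8.07e-07; adjusted p = 0.338 with an estimated correlation, 0.411 with fry) and 0.23 for ribosomal protein genes (adjusted p = 1.45e-06; adjusted p = 0.338 with an estimated correlation, 0.411 with fry), with 0 members called in either. For the photosynthesis list it was 0.64, with 0 of 9 members called on either adjustment (adjusted p = 0.00071; adjusted p = 0.284 with an estimated correlation, 0.351 with fry), a call also lost without late precursor replicate 1 (0.0927) or mature guard cell replicate 3 (0.0558). The autophagy mean was -0.38 (adjusted p = 0.0198; adjusted p = 0.338 with an estimated correlation, 0.411 with fry), a call also lost without late precursor replicate 2 (0.0766) or 3 (0.394) or mature guard cell replicate 3 (0.298), and with late precursor replicates 2 and 3 averaged (0.192). The G2/M, DNA replication, and ribosome and nucleolus lists did not pass (camera adjusted p = 0.251, 0.267 and 0.103, with 0 called on either adjustment), although the last of them passed without mature guard cell replicate 1 (0.0209). Plastid-encoded genes did not pass either (0.0955), but did without late precursor replicate 3 (1.2e-05) or mature guard cell replicate 1 (0.0303) or 2 (0.00146), and with late precursor replicates 2 and 3 averaged (0.00371).

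In all, 29 probe sets differed between mature guard cells and late precursors, 14 higher and 15 lower, and 1402 had an unadjusted p under 0.05. Alternatives gave 0 with only these groups, 14 with the replicate block, 16 with dim probe sets left out, 1008 with array weights, 88 with 1 weight per group and 3 with late precursor replicates 2 and 3 averaged, and 69, 3, 3, 18 and 9 without late precursor replicates 1, 2 and 3 and mature guard cell replicates 2 and 3. FAMA and BCAT4 did not pass with only these groups (adjusted p = 0.0691 for each), and CLE41 did not pass without late precursor replicate 2 (0.119) or 3 (0.0931), with only these groups (0.154) or with those replicates averaged (0.106). The GTR1 call was lost without late precursor replicate 2 (0.256) or 3 (0.25) or mature guard cell replicate 1 (0.142), 2 (0.0521) or 3 (0.151). GTR1 also did not pass with only these groups (0.129), the replicate block (0.106), dim probe sets left out (0.0698), cyclic loess (0.155), trend and robust settings (0.178) or averaging of late precursor replicates 2 and 3 (0.265). On simulated data 84% of 4-fold and 41% of 2-fold changes were found.

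The 4 lineage stages were tested together to ask which genes change anywhere along the lineage and where each is highest. By the printed range of stage means, SPCH, ATLP-1 and EXPB3 led the genes highest in early precursors, with ranges of at least 6.80, 4.96 and 4.02 on the log2 scale, since the lowest stage mean of each is near the background. LTI30 (10.49 ± 0.11), BGLU25 (8.09 ± 0.23) and HMT-1, a homocysteine methyltransferase gene (6.03 ± 0.14), led those highest in middle precursors (SD, n = 3). Each was lowest in early precursors. LTI30 averaged 10.3 ± 0.76 in mature guard cells and HMT-1 5.98 ± 0.20 in late precursors, so their highest stage is not resolved. FAMA, GT72B1 and CHX20 led those highest in late precursors, with ranges of at least 7.82 for FAMA, and of 4.97 and 4.65. Transgene transcripts can add to the SPCH range through the early sort and to the FAMA range through the late sort. GSTU25 (7.48 ± 0.76), the metallothionein gene MT1C (9.46 ± 1.00) and CCT2 (8.40 ± 0.06) led those highest in mature guard cells, each also lowest in early precursors. G2/M genes averaged 5.40 ± 0.32, 4.74 ± 0.17, 3.31 ± 0.16 and 3.42 ± 0.25 along the stages, autophagy genes 3.26 ± 0.18, 4.12 ± 0.10, 4.99 ± 0.39 and 4.61 ± 0.45.

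By the moderated F test 3522 probe sets, 16.8% of those measured, changed across the stages. Of these, 1214 were highest in early precursors, 538 in middle precursors, 1138 in late precursors and 632 in mature guard cells. The highest stage is the one with the highest mean, with no test against the next. Only 29 probe sets differed between late precursors and mature guard cells, so the split between these stages is mostly unresolved. The count was 2295 without late precursor replicate 2 and 2324 with late precursor replicates 2 and 3 averaged. On simulated data 87% of 4-fold and 49% of 2-fold changes were found. There, 58 calls, 29.9% of all calls in the simulation, were false. This false share, too, depends on how many probe sets truly change and does not carry over to the reported calls.

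**Figure D4:**
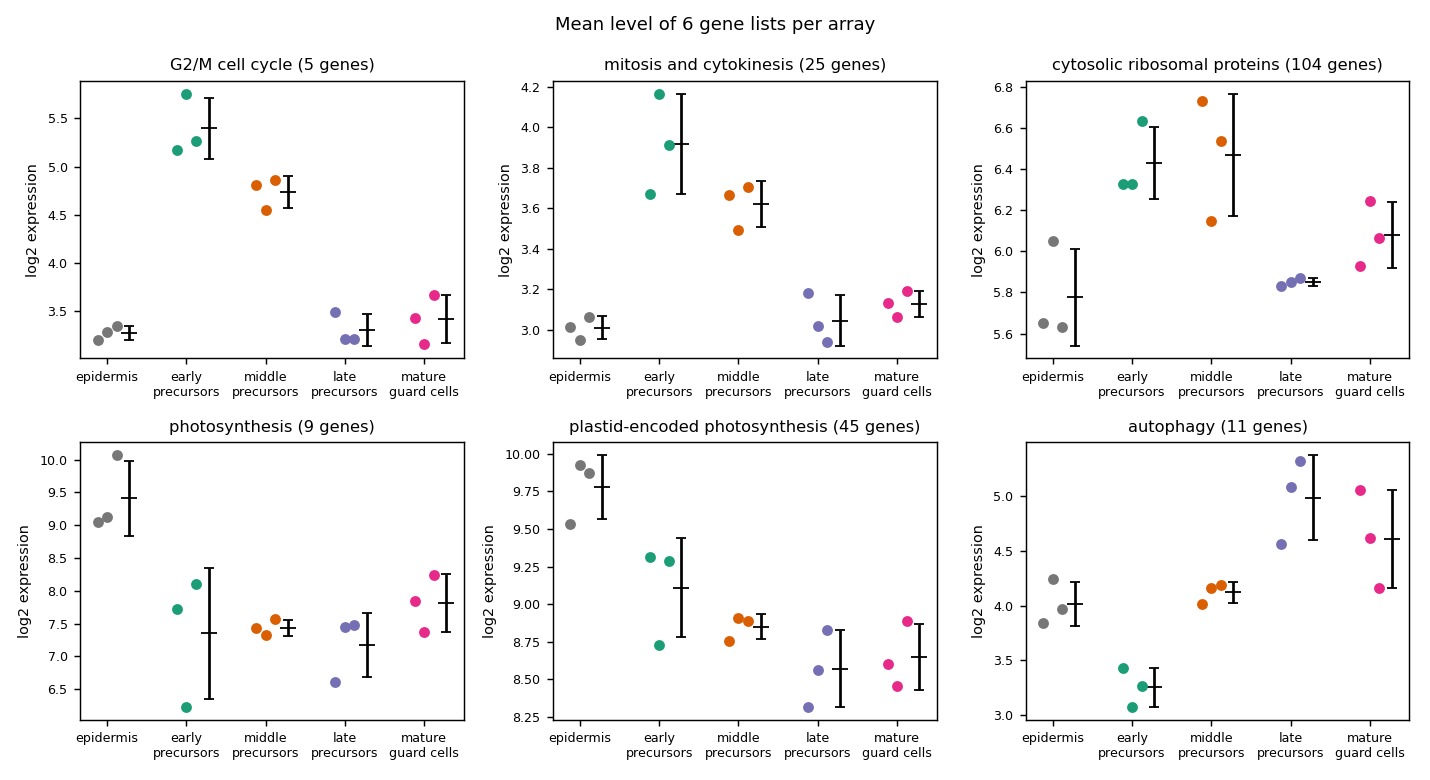
Mean log2 expression of 6 gene lists on each array (points), with group mean and SD (black bars, n = 3); the vertical axes differ and do not start at 0. G2/M genes average 5.40 in early and 4.74 in middle precursors against 3.28 in the epidermis, and photosynthesis genes 9.41 in the epidermis against 7.18 to 7.81 in the 4 stages.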

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

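The fits without the early precursor arrays, with 1 weight per group and with late precursor replicates 2 and 3 averaged were chosen after seeing the data. With only the compared groups in the fit, the counts of probe sets that passed were 273 for early precursors against the epidermis, 533 for mature guard cells against the epidermis, 362 for middle against early precursors, 1793 for late against middle precursors and 0 for mature guard cells against late precursors. Array weights gave 863, 2286, 4710 and 1468 for early, middle and late precursors and mature guard cells against the epidermis, and 770, 4256 and 1008 for the successive steps; late precursor replicate 2 took a weight of 9.61. With 1 weight per group the counts were 770, 1986 and 2626 for early, middle and late precursors against the epidermis, and 651, 1938 and 88 for the steps. Without the early precursor arrays they were 2496, 2924 and 1944 for middle and late precursors and mature guard cells against the epidermis, and 1412 for late against middle precursors. Averaging late precursor replicates 2 and 3 gave 858 against the epidermis, 327 against middle precursors, 3 between mature guard cells and late precursors and 2324 across the stages. For middle against early precursors, cyclic loess gave 1140 and a 2-fold minimum 1154. For mature guard cells against late precursors, the replicate block gave 14 and leaving out dim probe sets 16. All other counts were within 1.5 times the reported ones under these settings and with trend and robust empirical Bayes.

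Leaving out 1 array at a time gave 1168 to 2752 probe sets for early, 502 to 1077 for middle and 878 to 1622 for late precursors and 309 to 935 for mature guard cells against the epidermis. The steps ranged from 703 to 3765, 332 to 774 and 3 to 69, the count across the stages from 2295 to 4540, and the number of list calls from 48 to 54. Leaving out 1 array also removes residual degrees of freedom. Of 112 pairs of list and comparison 50 passed, 10 with an estimated correlation, 49 with fry and 46 to 51 under the other settings that keep all groups. With fry 10 calls were lost and 9 gained, and with cyclic loess 6 were lost and 5 gained besides the reversed ones. Those lost with fry were all 5 in mature guard cells against late precursors, the autophagy, ribosomal protein and protein folding lists in mature guard cells against the epidermis (0.093, 0.154 and 0.0772), nuclear chloroplast genes in middle against early precursors (0.649) and plastid-encoded genes in late against middle precursors (0.203). The 10 with an estimated correlation are the G2/M and mitosis lists in early and middle precursors against the epidermis and in late against middle precursors, the replication and histone, ribosomal protein and protein folding lists in middle precursors, and the pathogen list in early precursors.

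Camera's direction, which is relative to the other genes, reversed with cyclic loess for middle against early precursors in 3 lists; the cause was not tested. The mean log2 fold change turned from 0.04 to -0.35 for ribosomal proteins and from 0.18 to -0.20 for nuclear chloroplast function, while for ribosome and nucleolus it was negative both ways (-0.11 and -0.59). The nuclear chloroplast mean was also negative without early precursor replicate 2 (-0.10), where camera's direction did not change. A value that changed sign without passing either way is not counted as reversed. Of 331 pairs of named gene and comparison, 84 no longer passed and 4 newly passed with only the compared groups, 30 and 3 with cyclic loess, and 36 and 10 with array weights. Over 2154 results for a named gene in a comparison with 1 array left out, 416 calls were lost and 7 gained. No gene reversed in any of these settings. Replicate numbers showed little pairing of the arrays. Over 30 same-numbered pairs, r between residuals from the group means ranged from -0.105 to 0.168, above 0.1 in 3 pairs. Differently numbered arrays were not compared, so a weak pairing is not excluded. The 3'/5' measures of RNA quality could not be run without control probe sets, and the filter on probe set names removed 0. Without control probe sets the background could not be measured either, and the bound of 2.68 used for it is the highest array median.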

Other observations

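Among the tests in this part, random loss of transcripts was framed before its result was seen; those of guard cell RNA, of the shared spread, of stage distance and of mesophyll RNA, and the genes known only by locus code and STOMAGEN, were chosen after. Protein folding genes were higher in middle and late precursors than in the epidermis, by means of 0.78 (camera adjusted p = 0.00094; adjusted p = 0.0434 with an estimated correlation) and 0.95 (adjusted p = 0.00014; adjusted p = 0.0762 with an estimated correlation), with 0 and 2 of 18 called. In mature guard cells the mean was 0.52 (adjusted p = 0.012; adjusted p = 0.157 with an estimated correlation), lost with fry (0.0772), with cyclic loess (0.104), with dim genes left out (0.127) and without epidermis replicate 3 (0.106). They were also higher in middle than in early precursors by 0.58 (adjusted p = 0.0167; adjusted p = 0.146 with an estimated correlation), lost with cyclic loess (0.257) and with dim genes left out (0.15). In mature guard cells against late precursors the mean of -0.43 passed narrowly (adjusted p = 0.044; adjusted p = 0.338 with an estimated correlation, 0.411 with fry), and was lost without late precursor replicate 1 (0.0515), 2 (0.0766) or 3 (0.111) or mature guard cell replicate 3 (0.147). It was also lost with the replicate block (0.0551), with dim genes left out (0.1), without the early precursor arrays (0.0547) and with late precursor replicates 2 and 3 averaged (0.0747). Early precursors had lower dehydration and cold genes than the epidermis, 6 of 18 called with a mean of -0.80 (adjusted p = 0.000257; adjusted p = 0.136 with an estimated correlation), and lower pathogen and wound genes, 5 of 24 lower and 1 higher with a mean of -0.48 (adjusted p = 0.00195; adjusted p = 0.0318 with an estimated correlation; 0.0561 with cyclic loess). Examples are CML38, a calmodulin-like gene (-2.01, SE 0.29), and the transcription factor gene WRKY6 (-1.73, SE 0.30). Neither passed with only these groups in the fit (0.0741 and 0.0711). WRKY6 was higher in late precursors than in the epidermis (1.66, SE 0.30). In middle precursors against the epidermis the pathogen list (mean -0.31) did not pass with camera in the main fit. It passed as lower with fry (adjusted p = 0.00509), cyclic loess (0.00366), dim genes left out (0.0265), and without the early precursor arrays (0.0364) or epidermis replicate 3 (0.0291). From middle to late precursors it passed as higher only with fry (0.0281), cyclic loess (0.0329) and without late precursor replicate 1 (0.0158). UDP-glycosyltransferases were lower in middle precursors than in the epidermis (mean -0.20, adjusted p = 0.0164; adjusted p = 0.138 with an estimated correlation; 0.0569 without middle precursor replicate 3). They were higher in late than in middle precursors, 6 of 47 higher and 1 lower (mean 0.23, adjusted p = 0.00828; adjusted p = 0.124 with an estimated correlation). The expansin and XTH list (lowest camera adjusted p = 0.332) and the sugar transport list (lowest 0.0694, and 0.0385 without middle precursor replicate 2) passed with camera in none of the 7 comparisons, and single members moved both ways, such as XTH16, EXPA16 and EXPA15. The sugar transport list averaged 2.03 to 2.28 in the 5 groups, below the bound of 2.68, and passed with fry in early (0.0363) and middle precursors (0.0293) against the epidermis and in middle against early precursors (0.00305), so these genes cannot be said to have stayed level.

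Single genes of other cell types and of stress passed in few comparisons. STZ, the zinc finger gene also called ZAT10, stood between 8.24 and 8.95 and WRKY53 between 5.89 and 6.73 in all 5 groups, and neither passed in any comparison on either adjustment. The vascular sugar exporter gene SWEET11 (2.26 to 2.56), the cell cycle inhibitor gene SIM (1.85 to 2.07) and the guard cell kinase gene BLUS1 (AT4G14480; 1.81 to 2.63) passed in none over all probe sets. The trichome gene TRY averaged 3.84 ± 2.41 in early precursors (SD, n = 3) and at most 2.28 elsewhere. GIS fell by at least 0.93 on the log2 scale from early to middle precursors (adjusted p = 0.0112; 0.121 with only these groups in the fit). CR4, the epidermal receptor kinase gene ACR4, was at least 2.51-fold higher in middle precursors than in the epidermis (adjusted p = 0.0131; 0.0545 without middle precursor replicate 2). WSD1 (1.70 to 2.32), APL3 (1.83 to 2.17) and GH3.3 (2.06 to 2.71) passed in none over all probe sets. Over the 17 genes of these and the lineage lists, the 7 comparisons gave 4, 4, 1, 1, 6, 6 and 1 calls over all probe sets and 6, 5, 4, 2, 8, 8 and 2 adjusted over the list alone. Among genes with a locus code only, AT3G05730 had a range of 6.77 across the stages, from 3.43 ± 1.07 in early precursors to 10.21 ± 0.90 in mature guard cells. AT4G02940 averaged highest in late precursors at 9.62 ± 0.28, with 8.67 ± 0.54 in mature guard cells. AT5G23400 was highest in middle precursors at 6.12 ± 0.91, and AT3G51280 in early precursors at 8.28 ± 0.39. The highest stage was not tested against the next.

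Early precursor replicates spread more than those of the other groups. Probe sets more than 2 log2 units from both other arrays numbered 195, 310 and 246 above and 189, 212 and 46 below in early precursor replicates 1, 2 and 3, and at most 15 above and 42 below in any other array. Random loss of transcripts from little RNA was predicted to weigh least on bright probe sets. The SD ratio of early to other arrays was 2.42 in the brightest of 10 equal bins of probe sets. In the 4 bins below it the ratio was 1.92, a difference of 0.498 (bootstrap SE 0.0482, 1000 draws), opposite to the prediction. The bins rest on the mean of the other groups' arrays, so a probe set bright there can be low in early precursors. The SE is over probe sets, not arrays, so the test cannot decide on random loss. Guard cell RNA in replicate 1 is argued against. There, 37 guard cell probe sets averaged 3.57, 0.123 (SE 0.143 over probe sets) above the other replicates, and 6.95 in mature guard cells. Single genes go with it: GC1, which is not among the 37, stood at 6.99 in replicate 1 against 2.73 and 2.28, and CHX20, which is, at 6.46 against 4.88 and 4.79. A share of 0.269 of guard cell RNA would make up GC1 in replicate 1. It would need the 37 to lie higher by a mean of 2.02 (SE 0.203), which argues against that share. The cause of the GC1 difference is open. No biological explanation was tested.

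Few probe sets separated mature guard cells from late precursors. A shared spread estimate inflated by early precursors is argued against, since without those arrays the count was 42, and the smallest other count 1412. A smaller difference between these stages may account for the low count. Without the early arrays the SD of log2 fold changes above their error was 0.245, against 0.465 for the step before. With all arrays it was 0.128 against 0.415. The first ratio missed the bound set for that explanation, so it stays open. The second met the bound, but it rests on the same fold changes. It subtracts an error that includes the spread of the early arrays, so it adds no separate evidence. The tested step also rests on late precursor replicates 2 and 3, which may share a source, and the count was 3 when they were averaged.

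The photosynthesis list was lower in all 4 stages than in the epidermis at the preset correlation, but passed in none with an estimated correlation (adjusted p = 0.0509, 0.0805, 0.134 and 0.282). RNA from mesophyll in the epidermis sort could raise the epidermis, although the sort took cells with an epidermal ML1 reporter. STOMAGEN, a peptide gene made in mesophyll, averaged 2.69 in the epidermis, 0.109 above the median probe set, and was lower in 3 of the 4 stages (early by at least 0.92, adjusted p = 0.011; late by at least 1.14, 0.00362; mature by at least 0.76, 0.0486), each with a mean near the background, but did not pass in middle precursors (0.121). The early call was lost with only those groups in the fit (0.192), array weights (0.0624) or 1 weight per group (0.0728), and the mature call with only those groups (0.153), averaging of late precursor replicates 2 and 3 (0.0705), cyclic loess (0.127) and without epidermis replicate 2 (0.0807) or 3 (0.0914) or mature guard cell replicate 1 (0.116), 2 (0.0984) or 3 (0.129). A gene this close to the median probe set cannot decide, so mesophyll RNA and lower photosynthesis transcripts in the lineage itself cannot be told apart; guard cells hold chloroplasts as well, and all 9 genes are also in the nuclear chloroplast list.

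Other splits of the same arrays were refitted for each comparison. For 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real counts were 1868, 1157, 1679, 820, 1991, 799 and 29 in the order of the report, each reached by 1 split, the real one, and the highest of the other splits gave 18, 0, 0, 1, 1, 1 and 1. For lists the real numbers of calls were 10, 10, 5, 7, 5, 8 and 5, with 1, 2, 4, 2, 2, 2 and 3 splits giving as many and 8, 10, 8, 7, 6, 8 and 5 as the highest others. Across the stages, 1 of 100 drawn splits, the real one, reached 3522, and the highest other gave 1677. That share is under 0.05 and argues against chance, but does not exclude it. The splits treat arrays as interchangeable, although the early precursor arrays spread more than the others.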
